A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

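Genomic DNA of a pooled Saccharomyces cerevisiae library was compared on 3 two-colour tag arrays, 1 each for cycloheximide, rapamycin and tunicamycin. In a variomics library each strain carries many sequence variants of 1 gene and a pair of short DNA tags that mark the strain. Per the labels, the pool was that of essential genes, the drug-selected DNA was in the Cy5 channel and untreated DNA of the same pool was in the Cy3 channel. Per the labels' protocols, cells were sporulated and grown in selective medium, DNA was extracted with a MasterPure yeast kit, and the tag regions were amplified with universal primers of which 1 carried the dye. The sample descriptions give 30 ng for cycloheximide, 20 ng for rapamycin and 3 "vg" for tunicamycin, and name the rapamycin sample "single" where the others are named pool. What these words stand for is not given in the sources used here, so a difference between rapamycin and the other arrays may also come from another library or kind of selection.

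The values analysed were the authors' deposited log2 ratios, 1 per spot and array, for 22575 spots. Base 2 was taken from the values themselves, of which many equal the log2 of a ratio of small whole numbers. The scanner, its software, the background correction and any normalization are not given in the sources used here. The measured medians were -0.74, -1.32 and -0.87 for cycloheximide, rapamycin and tunicamycin, so the deposited values had not been centred on their median. The file does not state the direction of the ratio. It was taken as Cy5 over Cy3, drug-selected over untreated, which is likely from the dyes in the labels and from the essential-gene tags, most of which lay on 1 side of the array median on all 3 arrays. Signals of the channels were not analysed here, so no background threshold or brightness filter could be applied. The number of arrays limits the precision.

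A single value, 16.61, stood on 739, 196 and 526 spots of the cycloheximide, rapamycin and tunicamycin arrays. It equals the log2 of 100000 and lies far above the highest other values of 4.46, 9.10 and 7.67. It was read as a code, and these spots were left out as not measured. The design fixed before the data were examined had not foreseen a code and would have averaged it as a ratio, so this is a departure from it, made before any gene was ranked. The version with the code kept was run as an alternative. Empty values stood on 3156, 2821 and 2951 spots, which left 18680, 19558 and 19098 measured spots.

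Probes were named through a platform annotation of the array. It named 18794 probes with 1 gene each and 0 with several, and left 3781 unnamed. Of 5325 genes, 5321 had an identifier in the RefSeq gene table of assembly R64, which was used for symbols, locus tags and gene neighbours only. No coordinates are printed because the array values carry no genome build. Exactly 2 probes named 4439 genes, 12 probes named 781 genes and other numbers named 105 genes. The annotation does not say which probe is which tag of a strain.

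The array median was subtracted from each spot, and a gene value is the mean of its measured probes. Because most tags on the array mark genes outside the essential pool, a value of 0 stands for the ratio of background spots. The spread unit of an array is its median absolute deviation of gene values, scaled to an SD. It was 0.924, 1.06 and 0.914 on the log2 scale for cycloheximide, rapamycin and tunicamycin. A gene was called enriched or depleted when it had at least 2 measured probes, its value lay at least 3 units above or below 0, and each probe lay at least 2 units to the same side. These are rules of size. With 1 array per drug and no replicate, no p-value was computed and no difference between drugs was tested. Each SD printed is that between the probes of a gene on 1 array, and n is the number of probes. It may hold an offset between lower- and higher-numbered probes as well as scatter. Under cycloheximide many depleted genes had the higher-numbered probe lower, as CCT4 at -3.34 and -4.80, while GLN1 at -6.17 and -5.54 went the other way. Under rapamycin the only measured probe was often the lower-numbered one, as in CCT4 but not in CDC45.

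The genes named follow a rule fixed before the data were examined. It takes, per drug, up to 12 highest enriched and the 6 lowest depleted genes, the textbook drug targets FPR1, TOR1, TOR2, ALG7 and RPL28, up to 3 members of each fixed gene list with the largest absolute value, genes enriched under all drugs, and the 5 genes with the largest difference in each direction for each pair of drugs. The 18 lists cover the rapamycin target with the TOR complexes, multidrug resistance, non-essential amino acid and adenine synthesis as background, and 15 groups of essential genes with 283 genes on the array. The multidrug resistance genes are not essential, and the TOR list is not limited to essential genes. A gene outside the essential pool has no strain to select, so its lack of a call shows nothing about its variants. List medians were placed as percentiles among 10000 random lists of the same size, drawn from all genes and, as an addition, from the union of the essential lists. The random lists could not be matched on signal. Rank correlations across genes are descriptions, since genes are not replicates. The untreated DNA may be the same on all arrays. Its share in correlations and overlaps between drugs could not be simulated or split from ratios alone, so part of both may come from it.

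The rule was tested on simulated data drawn from the non-essential list's spots of each array, with 50 genes shifted per size. Among simulated genes with at least 2 measured probes, a shift of 4 upward was recovered for 96.6% on cycloheximide, 70.7% on rapamycin and 100% on tunicamycin, and a shift of 6 upward for 100%, 92.5% and 100%. These shares used the spread unit of the simulated values. Recovery with the larger unit of the real arrays was not computed and could only be equal or lower. Among 3797, 4237 and 3643 unshifted genes, 6, 4 and 12 were called enriched and 8, 36 and 9 depleted with the spread unit of the simulated values, which was 0.675, 0.914 and 0.701. With the larger unit of the real arrays it was 0, 1 and 0 enriched and 1, 25 and 0 depleted. The draws held only spots of the non-essential list, so these counts are no false-call rate for strains of the pool. As a second check, the probes of the 4439 genes with 2 probes were re-paired at random 100 times. The alternatives varied the centring, between-array normalization, threshold, probe rule, gene summary, spread unit, direction and treatment of exact 0, and, chosen after seeing the data, the code, the probe minimum and 2 choices of reference genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.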

Results

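Abundance of tagged yeast strains under drug selection was measured relative to the untreated pool on 1 array for each of 3 drugs. Cycloheximide blocks translation elongation on the large ribosomal subunit, rapamycin inhibits TOR kinase bound to the prolyl isomerase Fpr1, and tunicamycin inhibits Alg7, the enzyme of the first step of N-linked glycan synthesis. The arrays were set up to find strains of an essential-gene variomics library that resist a drug. Gene values could be computed for 5192 genes on the cycloheximide array, 5110 on the rapamycin array and 5232 on the tunicamycin array, and 4121, 4015 and 4169 of these had at least 2 measured probes. All values are log2 ratios of drug-selected over untreated DNA relative to the array median, with the SD between probes of 1 array and the number of probes n. No replicate exists for any drug.

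Most strains of the essential lists lay far below the array median after each selection, and few genes were enriched. Of the members of the 15 essential lists with at least 2 measured probes, 165 of 272 (60.7%) were depleted under cycloheximide, 63 of 121 (52.1%) under rapamycin and 146 of 245 (59.6%) under tunicamycin. Over all members with a measured probe, 282, 244 and 280 genes, the medians were -3.30, -5.41 and -4.14, and over those with at least 2 they were -3.32, -4.38 and -4.14. Every list median given is over all members with a measured probe, so it can cover more genes than the count of depleted members beside it. In the non-essential list of amino acid and adenine synthesis genes, which served as background, 0 of 42, 0 of 47 and 0 of 41 genes were depleted and 0 were enriched, with medians of 0.03, 0.10 and 0.28. Its members with the largest values included TRP4 (YDR354W) at 2.32 (n = 1) under cycloheximide and -2.81 ± 2.18 (n = 2) under rapamycin, and SER1 (YOR184W) at -2.45 (n = 1) under tunicamycin. Over all genes, 625 were depleted under cycloheximide, 259 under rapamycin and 569 under tunicamycin, with median values of -3.82, -6.52 and -5.49, which are 14.1-fold, 91.5-fold and 45.0-fold lower. When probes were re-paired at random, a mean of 149, 93.3 and 145 genes passed the depletion rule, against 621, 254 and 566 observed among genes with 2 probes.

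**Figure D1:**
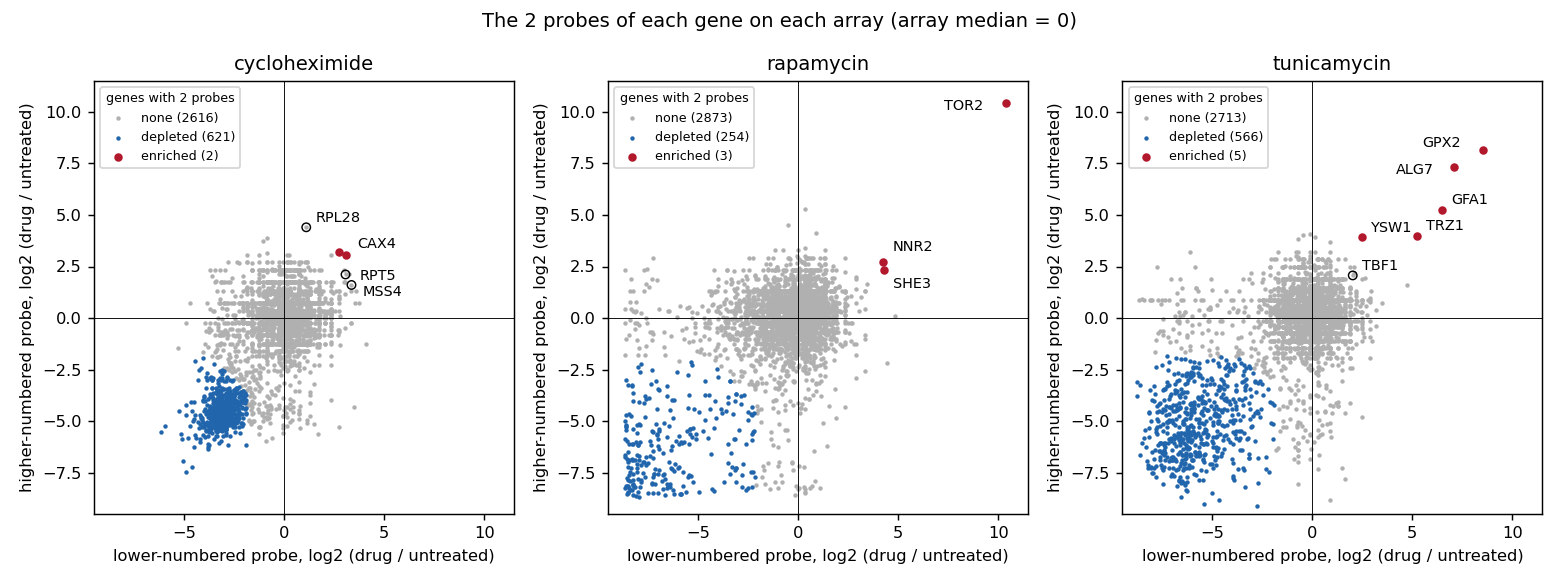
Each point is a gene with 2 measured probes, with the log2 ratio (drug over untreated, array median 0) of its lower-numbered probe on the x axis and of its higher-numbered probe on the y axis, for 1 array per drug. Depleted genes (621, 254 and 566, blue) fill the lower left of each panel, and the enriched genes (2, 3 and 5, red) lie in the upper right, TOR2 at 10.36 and 10.43.

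On the cycloheximide array 2 genes were enriched. CAX4 (YGR036C), a dolichyl pyrophosphate phosphatase, had a value of 3.08 ± 0.03 (SD, n = 2). PET117 (YER058W), an assembly factor of cytochrome c oxidase, had 2.98 ± 0.34 (n = 2). Neither is a member of the essential lists, and the sources used here do not say whether the pool held strains of them. RPL28 (YGL103W), which encodes a 60S ribosomal protein in which cycloheximide resistance mutations are known, had the 6th highest gene value, 2.76 ± 2.33 (n = 2), and was not called because its probes stood at 1.11 and 4.40. In CAX4 and in PET117, 1 of the 2 probes equalled, to 3 decimals, the log2 of a ratio of whole numbers up to 10, as 66.5% of the measured spots on this array did, so no fold is given for them. Random re-pairing of probes gave a mean of 0.51 and up to 4 enriched genes, a range that holds the count of 2. With the spread unit of the array 0 unshifted genes were called enriched in simulation. That simulation drew only on the non-essential list, where the highest false call with its own smaller unit was 2.38. Its 0 therefore gives no false-call rate for other spots. Neither gene was called without centring, at the stricter threshold or with coded spots kept. With coded spots kept CAX4 had 3.04 and PET117 2.93. The spread unit rose from 0.924 to 1.01 and the array median from -0.737 to -0.692. For PET117 the larger unit alone ended the call, and for CAX4 both changes together did. CAX4 had 6.87 and PET117 3.65 after quantile normalization, and 37 genes were depleted at the stricter threshold.

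The 6 lowest depleted genes under cycloheximide were TAF6 (YGL112C) at -6.20 ± 1.81, CEF1 (YMR213W) at -5.98 ± 1.32, MMF1 (YIL051C) at -5.92 ± 1.88, GLN1 (YPR035W) at -5.86 ± 0.45, NUT2 (YPR168W) at -5.61 ± 0.50 and IRA1 (YBR140C) at -5.48 ± 0.53, each with n = 2. TAF6 is a subunit of TFIID and SAGA, CEF1 a splicing factor, and GLN1 glutamine synthetase. Among the 60S ribosomal proteins, to which RPL28 belongs, 5 of 10 were depleted and 0 enriched, with a median of -2.79, and RPL10 (YLR075W) at -5.39 ± 1.25 and RPL17A (YKL180W) at -5.11 ± 1.01 were the lowest. Of the 40S proteins 4 of 6 were depleted (median -3.71), led by RPS13 at -4.64 ± 1.27. Of the translation factors 14 of 23 were depleted (median -3.14), with HYP2, the eIF5A protein, at -4.64 ± 0.93 and TIF11 at -4.24 ± 1.01. Of the TOR list 3 of 12 were depleted, among them LST8 (YNL006W) at -4.24 ± 1.69 and AVO1 (YOL078W) at -3.88 ± 0.72, and its median was 0.52. That list is not limited to essential genes, so its median may rest on genes without a strain in the pool.

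The other essential lists had no enriched member on this array. In N-glycosylation 14 of 20 members were depleted (median -3.67), with SEC53 at -4.96 ± 1.64 and WBP1 at -4.42 ± 1.01. In GPI anchor synthesis 12 of 19 were depleted (-3.25), with GPI17 at -4.69 ± 1.13. In the proteasome it was 14 of 25 (-2.95), with PUP1 at -4.55 ± 1.97. In ER translocation it was 9 of 12 (-3.66), with SEC61 at -4.01 ± 1.477. Vesicle transport had 11 of 25 (-2.97) and exocytosis 9 of 14 (-3.17), with RET2 at -4.38 ± 1.03 and SEC15 at -4.09 ± 1.02. RNA polymerases had 15 of 25 (-3.54), the CCT chaperonin 4 of 7 (-3.18) and DNA replication 21 of 32 (-3.44), with RPB11 at -4.17 ± 1.07, CCT7 at -4.14 ± 1.12 and PRI1 at -5.12 ± 1.27. Ergosterol and isoprenoid synthesis had 8 of 15 (-3.29), the RNA exosome 6 of 10 (-3.15) and splicing 19 of 29 (-3.36), with MVD1 at -4.28 ± 1.52, RRP43 at -4.59 ± 1.23 and PRP21 at -5.30 ± 0.71. In the multidrug resistance list 0 of 6 genes were called, and its transcription factor PDR1 had 0.43 ± 0.68 (n = 9). These genes are not essential and so lie outside the pool of the labels, and the 0 does not show whether their variants resist.

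On the rapamycin array TOR2 (YKL203C), 1 of the 2 TOR kinases of yeast, had the highest value of any gene, 10.40 ± 0.04 (n = 2), which is 1347-fold higher than the array median. Its probes stood at 10.36 and 10.43, and the size of the fold rests on the untreated channel, whose signal was not analysed here. NNR2 (YKL151C), a repair enzyme of hydrated NADH and NADPH, had 3.48 ± 1.09 (n = 2) and SHE3 (YBR130C), an adaptor of mRNA transport to the bud, 3.31 ± 1.40 (n = 2). These 3 were the enriched genes. NNR2 and SHE3 are not members of the essential lists, and the pool may have held no strain of either. TOR1, the other TOR kinase, had -0.11 ± 1.40 over 12 probes, and FPR1 was not analysed here because no named probe carried it. The sources used here do not say whether the pool held a TOR1 strain, so its value cannot show whether TOR1 variants resist. In SHE3 1 probe equalled the log2 of a ratio of whole numbers up to 10. Random re-pairing gave a mean of 0.26 and up to 2 enriched genes, and with the spread unit of the array 1 unshifted gene was called enriched in simulation, at 5.17, above the values of NNR2 and SHE3. With the spread of the non-essential list as the unit SHE3 was not called. TOR2 alone remained enriched without centring and at the stricter threshold, and its value was 6.86 after quantile normalization.

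The lowest depleted genes under rapamycin were TUB4 (YLR212C) at -8.55 ± 0.04, GPI8 (YDR331W) at -8.48 ± 0.01, IPI3 (YNL182C) at -8.47 ± 0.05, NAB2 (YGL122C) at -8.45 ± 0.30, SRP21 (YKL122C) at -8.44 ± 0.23 and DRS1 (YLL008W) at -8.39 ± 0.05, each with n = 2. TUB4 encodes gamma-tubulin, GPI8 the catalytic subunit of the GPI transamidase, and NAB2 a poly(A)-binding protein. In the TOR list 1 of 11 members was enriched (TOR2) and 3 were depleted, AVO1 of TOR complex 2 among them at -7.34 ± 0.996 (n = 2), while LST8 of both complexes had -8.44 in its only measured probe. The median of this list, which is not limited to essential genes, was -0.17 and may rest on genes without a strain in the pool. In the multidrug resistance list, whose genes are not essential, 1 of 8 was depleted, the transcription factor PDR3 (YBL005W) at -3.51 ± 1.71 (n = 2). Such a call can come from background spots, since 25 unshifted genes were called depleted in simulation with the unit of this array. On this array 0 measured spots had a deposited log2 ratio below -10 and 406 lay between -10 and -9, so the depth and order of the lowest genes may be bounded by that edge. Empty values held 35.7% of the spots of the essential lists on this array, against 10.5% in the non-essential list, and 340 genes with a single measured probe lay at or below -3 units. The count of depleted genes was 599 when 1 measured probe sufficed.

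Fewer members of the essential lists had at least 2 measured probes under rapamycin than under the other drugs. Of the N-glycosylation members 4 of 6 were depleted (median -7.28), with PCM1 at -8.20 ± 0.46, and of the GPI anchor members 6 of 8 (-6.89), with GPI1 at -8.32 ± 0.26. Of the 60S proteins 0 of 4 were called (-2.78), while RPL10 at -8.55, RPL17A at -7.87 and RPL3 at -7.56 had 1 measured probe each and could not be called. Of the 40S proteins 1 of 2 (-4.45), RPS15 at -5.05 ± 3.98, and of the translation factors 6 of 8 (-5.67). The proteasome had 5 of 11 depleted (-5.59) and ER translocation 3 of 6 (-7.24). Vesicle transport had 5 of 13 (-4.86), with SEC13 at -8.20 ± 0.03, and exocytosis 2 of 5 (-5.96), with SEC9 at -7.92 ± 0.13. RNA polymerases had 7 of 12 (-4.54), the CCT chaperonin 1 of 4 (-4.11), CCT7 at -7.48 ± 0.52, and DNA replication 11 of 17 (-5.96). Ergosterol synthesis had 3 of 8 (-4.87), with ERG20 at -7.26 ± 1.99, the RNA exosome 2 of 4 (-5.85), with RRP45 at -7.69 ± 0.08, and splicing 7 of 13 (-5.94).

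On the tunicamycin array 5 genes were enriched, and ALG7, the target of the drug, was the second of them. GPX2 (YBR244W), a glutathione peroxidase, had 8.34 ± 0.29 (n = 2), 323-fold higher than the array median, and ALG7 (YBR243C), its neighbour on the chromosome, 7.19 ± 0.19 (n = 2), 146-fold higher. GFA1 (YKL104C), which catalyses the first step of the synthesis of UDP-GlcNAc, a substrate of Alg7, had 5.87 ± 0.86 (n = 2), 58.5-fold higher. TRZ1 (YKR079C), the tRNA 3'-processing endonuclease, had 4.61 ± 0.88 (n = 2), 24.4-fold higher, and YSW1 (YBR148W), a spore-specific protein, 3.19 ± 1.03 (n = 2). In YSW1 1 probe equalled the log2 of a ratio of whole numbers up to 10. GPX2, TRZ1 and YSW1 are not members of the essential lists, and whether the pool held their strains is not given here. Random re-pairing gave a mean of 1 and up to 4 enriched genes, and with the spread unit of the array 0 unshifted genes were called enriched in simulation. The simulated spots came from the non-essential list alone, where the highest false call with its own smaller unit was 2.57. This 0 is no false-call rate for other spots. GPX2, ALG7, GFA1 and TRZ1 remained enriched without centring and at the stricter threshold, and YSW1 did not, and after quantile normalization GPX2 had 6.87 and ALG7 6.07.

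The lowest depleted genes under tunicamycin were NSE1 (YLR007W) at -7.78 ± 0.34, RPC53 (YDL150W) at -7.77 ± 0.41, SAH1 (YER043C) at -7.75 ± 0.08, CDC36 (YDL165W) at -7.75 ± 0.69, PGA3 (YML125C) at -7.74 ± 0.30 and NCB2 (YDR397C) at -7.69 ± 0.56, each with n = 2. RPC53 is a subunit of RNA polymerase III and SAH1 the S-adenosylhomocysteine hydrolase. The N-glycosylation list held 2 enriched members of 19, ALG7 and GFA1, and 10 depleted ones, among them PCM1 (YEL058W) at -6.47 ± 1.29 and RER2 (YBR002C) at -6.25 ± 0.61. Its median was -3.35. Ergosterol and isoprenoid synthesis had a median of -5.89, with 7 of 11 members depleted, among them NCP1 (YHR042W) at -7.36 ± 0.45 and MVD1 (YNR043W) at -7.13 ± 1.03.

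In the remaining lists no member was enriched under tunicamycin. GPI anchor synthesis had 14 of 19 depleted (median -4.51), with GWT1 at -6.37 ± 1.90 and GPI11 at -6.18 ± 2.27. The 60S proteins had 4 of 9 (-2.37), with RPL10 at -7.12 ± 0.31, the 40S proteins 3 of 5 (-4.66), with RPS3 at -7.23 ± 1.21, and the translation factors 11 of 22 (-3.67), with HYP2 at -6.29 ± 1.63. The proteasome had 15 of 25 (-4.07), with PUP3 at -7.40 ± 0.20, ER translocation 8 of 12 (-4.65), with SEC61 at -6.72 ± 1.52, vesicle transport 12 of 22 (-4.33), with SEC17 at -7.03 ± 0.16, and exocytosis 9 of 11 (-4.99), with SEC9 at -6.75 ± 1.56. RNA polymerases had 13 of 23 (-3.77), the CCT chaperonin 3 of 6 (-4.29), with CCT4 at -6.11 ± 1.39, and DNA replication 15 of 26 (-3.80), with ORC5 at -6.71 ± 0.79. The RNA exosome had 6 of 9 (-4.10), with MTR3 at -7.28 ± 0.39, and splicing 16 of 26 (-4.0015), with PRP38 at -7.35 ± 1.43. In the TOR list 3 of 10 were depleted, AVO1 at -5.23 ± 0.67, LST8 at -5.07 ± 2.04 and KOG1 (YHR186C) at -3.41 ± 0.09, and its median was -0.09. In the multidrug resistance list 0 of 8 were called, with YAP1 at 1.01 ± 0.19 (n = 2). Neither of these lists is an essential list, so a member without a call may have had no strain in the pool. Every essential list had a median below 0 on each of the 3 arrays. Among random lists drawn from the essential lists, the 45 medians had percentiles between 1.12 (ergosterol synthesis under tunicamycin) and 97.5 (60S proteins under tunicamycin). How wide a range 45 random lists would span was not computed, so neither end is read as a property of its list. Ergosterol synthesis stood at 53.1 and 66.5 under cycloheximide and rapamycin, and the 60S proteins at 82.2 and 96.8.

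**Figure D2:**
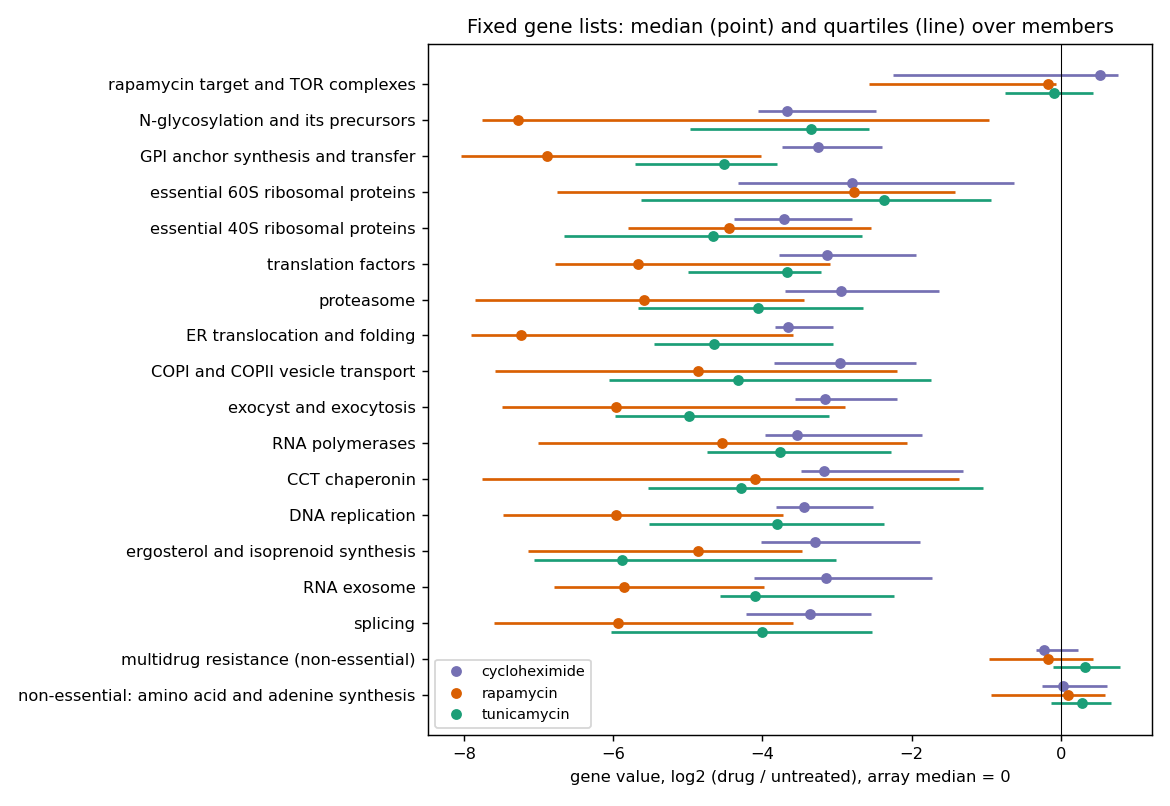
Median (point) and quartiles (line) over the members with a measured probe of each fixed gene list of the gene value (x axis, log2 drug over untreated, array median 0), in 1 colour per array. The medians of the essential lists lie below 0, and those of the non-essential synthesis list lie at 0.03, 0.10 and 0.28 for cycloheximide, rapamycin and tunicamycin.

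The drugs were compared to ask whether they selected the same strains. No gene was enriched on more than 1 array. Independent lists as short as these would share 0.0019, 0.0024 and 0.0013 genes for cycloheximide with rapamycin, cycloheximide with tunicamycin and rapamycin with tunicamycin, so the 0 shared does not answer the question. TOR2, at 10.40 under rapamycin, had 0.94 ± 0.29 (n = 2) under cycloheximide and 0.29 (n = 1) under tunicamycin. ALG7, at 7.19 under tunicamycin, was depleted under cycloheximide at -4.30 ± 0.74 (n = 2) and had -7.47 (n = 1) under rapamycin. GPX2 was depleted under cycloheximide at -3.16 ± 0.21 and under rapamycin at -5.78 ± 3.56. GFA1 was depleted under cycloheximide at -4.02 ± 1.24 and had -7.85 (n = 1) under rapamycin, and TRZ1 had -2.93 ± 1.82 (n = 2), which was not called, and -8.65 (n = 1). TBF1 (YPL128C), a telomere-repeat binding factor, was depleted under cycloheximide at -3.99 ± 0.90 and rapamycin at -8.16 ± 0.54, and had 2.04 ± 0.03 (n = 2) under tunicamycin, which was not called.

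Other genes with large differences had higher values under cycloheximide than under another drug. MSS4 (YDR208W), the phosphatidylinositol-4-phosphate 5-kinase, had 2.49 ± 1.25 under cycloheximide and -7.28 ± 1.47 under tunicamycin. RPT5 (YOR117W), a proteasome ATPase, had 2.59 ± 0.68 and -5.80 ± 0.91. PRO3 had 1.82 ± 0.87 and -6.38 ± 1.49, ERG10 0.75 ± 2.92 and -7.12 ± 1.87, and YPT1 0.81 ± 1.29 and -6.41 ± 0.07. None of these cycloheximide values, those of MSS4 and RPT5 included, was called. Between cycloheximide and rapamycin, PAB1 (YER165W), the poly(A)-binding protein, had -0.47 ± 1.35 and -8.15 ± 0.14, EAF5 -1.54 ± 0.97 and -8.07 ± 0.29, GPI1 -2.54 ± 2.18 and -8.32 ± 0.26, and GPI14 -1.46 ± 1.57 and -6.96 ± 1.69. ILT1 had 2.03 ± 1.001 and -3.01 ± 0.04, of which neither was called. In the opposite direction, ISU1, ALT1, AQR1 and CCM1 had -1.90, -1.62, -1.06 and -1.35 under cycloheximide and 1.33, 1.60, 2.01 and 1.476 under rapamycin, and none of these 8 values was called.

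Between rapamycin and tunicamycin, VPS75 had -5.39 ± 0.04 and -0.13 ± 1.41, NSA2 -6.54 ± 1.56 and -1.19 ± 0.83, and ACC1, the acetyl-CoA carboxylase, -5.39 ± 0.04 and -0.34 ± 2.17, each depleted under rapamycin. ALT1, an alanine transaminase, had 1.60 ± 0.19 and was depleted under tunicamycin at -2.83 ± 0.29. NNR2 had 3.48 ± 1.09 and -1.09 ± 0.05, SUT1 2.28 ± 0.07 and -1.69 ± 0.34, TMA10 1.30 ± 0.65 and -2.30 ± 2.58, and MPS3 -0.41 ± 4.02 (n = 3) and -3.79 ± 0.99 (n = 2), the last of these depleted. None of the differences between drugs could be tested with 1 array each, and whether the rapamycin sample came from the same pool and kind of selection as the others is not given in the sources used here.

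Depleted genes were shared between the drugs. Among genes with at least 2 measured probes on both arrays, cycloheximide and rapamycin shared 177, out of 181 and 244 depleted genes. Cycloheximide and tunicamycin shared 512, out of 582 and 568, and rapamycin and tunicamycin 142, out of 231 and 148. Independent lists over all genes would share 14.3, 98.1 and 10.8, but most of those genes are not essential, and 0 genes of the non-essential background list were depleted, so membership of the pool alone would raise the shared counts above these. Within the essential lists, 47, 130 and 34 genes were depleted in both, where independent lists over the 111, 236 and 98 genes with at least 2 measured probes on both arrays would share 26.9, 93.4 and 19.1. Of 2542 genes with at least 2 measured probes on all arrays, 121 were depleted on all 3, 64 on 2 and 43 on 1. Spearman's rho across genes was 0.373 over 4980 genes for cycloheximide and rapamycin, 0.475 over 5107 genes for cycloheximide and tunicamycin and 0.360 over 5021 genes for rapamycin and tunicamycin. Within the essential lists it was 0.704 over 243 genes, 0.595 over 279 and 0.713 over 241. Part of these overlaps and correlations may come from untreated DNA shared by the arrays, and genes are not independent replicates.

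**Figure D3:**
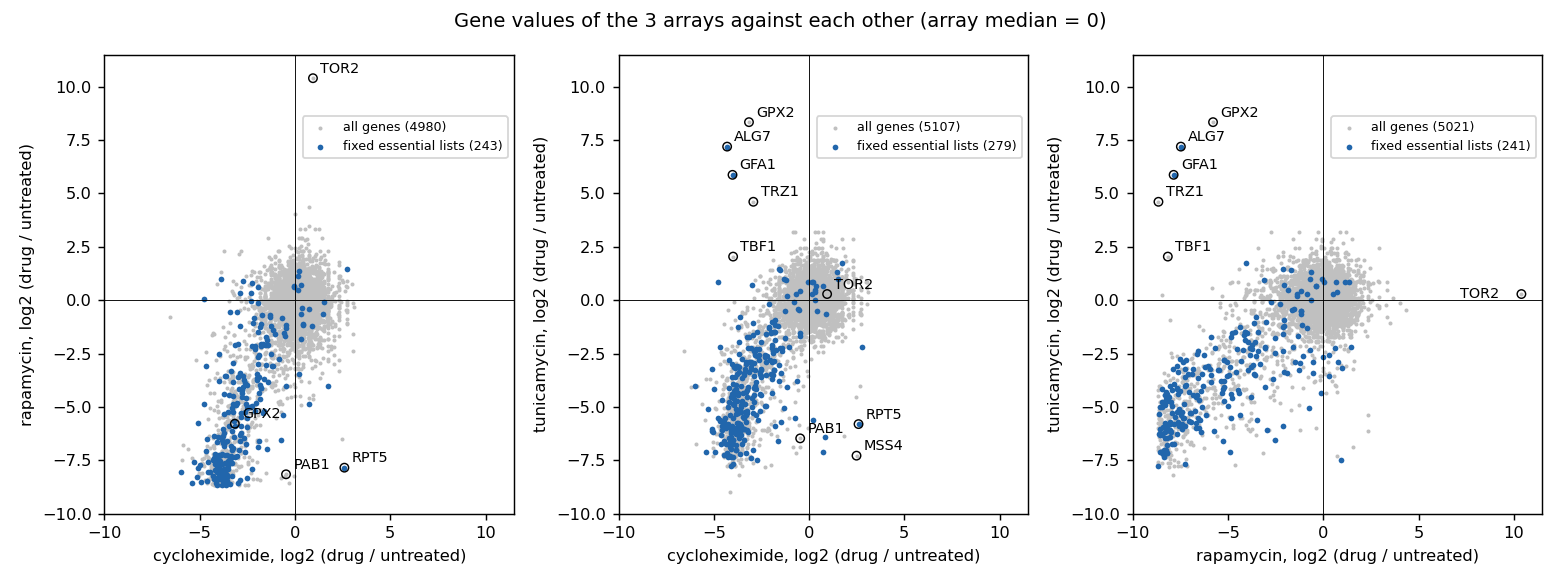
Gene values (log2 drug over untreated, array median 0) of 1 array against another, for 4980, 5107 and 5021 genes (grey) and the 243, 279 and 241 of them in the essential lists (blue). Most essential-list genes lie low on both axes, while GPX2, ALG7, GFA1 and TRZ1 lie high under tunicamycin and below 0 under the other drugs, and TOR2 lies high under rapamycin alone.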

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

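All tests of explanations in this part were chosen after the values they explain had been seen. The differences between drugs given here were not tested, since each drug has 1 array.

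Genes enriched under 1 drug and depleted under another were singled out because every probe moved one way on 1 array and the opposite way on the other. GPX2 lay 11.49 higher on the log2 scale under tunicamycin than under cycloheximide and 14.12 higher than under rapamycin. ALG7 lay 11.49 higher and GFA1 9.89 higher under tunicamycin than under cycloheximide. The unnamed probes 5796 and 16767, which the comparisons by gene do not use, had a mean of 3.93 ± 0.72 (n = 2) under cycloheximide, with 4.43 and 3.42, and of 5.32 ± 0.56 (n = 2) under tunicamycin, with 4.93 and 5.72. They passed the rule for enriched genes on both arrays, as 1 of 621 unnamed probe pairs, and no gene named on the array did so on more than 1.

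GPX2 is not essential, yet its tags followed those of its chromosomal neighbour ALG7 on all 3 arrays. Spill-over between spots with neighbouring numbers is argued against, because the median of 4230 spots numbered 1 above or below those of called genes was 0.076 spread units in the direction of the called gene, and of 9 measured values numbered next to the GPX2 and ALG7 spots 0 lay beyond 2 units. Whether consecutive numbers lie side by side on the array is not given in the sources used here, so spill-over between spots that touch stays untested. A single strain or tag pair read under both names stays open, because GPX2 lay 1.15, 1.69 and 1.15 above ALG7 under cycloheximide, rapamycin (where ALG7 had 1 probe) and tunicamycin, at most 1.6 units and within the bound of 2, but GFA1, compared after that was known, lay within 1.45 units of ALG7 too. Under rapamycin the GPX2 probes stood at -8.302 and -3.265, and the only measured ALG7 probe, the lower-numbered one, at -7.471. The 1.69 there therefore rests on the higher-numbered GPX2 probe, and on the lower-numbered probes GPX2 lay below ALG7. Variation in the GPX2 strain itself as a biological source was not tested.

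The RPL28 probes stood at 1.11 and 4.40 on the cycloheximide array, where the higher spot ranked 3rd of all measured spots. A probe that does not respond on any array may account for the low one, since its largest value over the 3 arrays was 1.4 units. Under tunicamycin it stood at 0.73 while the other probe stood at -5.15. A flaw of 1 spot cannot be told apart from a true rise of the strain, because 0 spots of the non-essential list reached the value of the high spot and the lower probe shows no rise beyond 2 units. Resistance through RPL28 variants stays an untested biological explanation.

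TOR2 lay near the array median under cycloheximide and tunicamycin although most essential strains lay far below it. Tags without any signal are argued against by 9.88 units, the largest TOR2 value, on the rapamycin array. A TOR2 strain too rare in the untreated pool to be read may be the reason, since 3 of its 3 measured values on those arrays equal, to 3 decimals, the log2 of a ratio of whole numbers up to 10, as dim spots would give. Such values made up 13.5% and 15.6% of the essential-list spots on the cycloheximide and tunicamycin arrays and 76.9% and 71.8% of the non-essential ones. Survival of TOR2 strains under those drugs was not tested and stays open.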

How the results depend on the processing

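The alternatives with the code kept, with 1 probe sufficing and with other reference genes were chosen after seeing the data. Of 171 recomputed counts, correlations and list results, 130 stayed within 1.5 times the value reported, or within 0.05 for a correlation, and 41 moved. Of 110 recomputed values of single enriched genes and RPL28, 95 moved by no more than the SD between probes, 15 moved further and none changed sign. Many could not move. Both other thresholds, the mean alone, the other spread unit and the lower probe minimum act on calls only. They leave gene values, correlations and list medians as they were. For genes with 2 probes the median of spots is the mean. The counts that stayed are therefore no measure of robustness. Quantile normalization moved TOR2 to 6.86, GPX2 to 6.87, ALG7 to 6.07, PET117 to 3.65 and CAX4 to 6.87, by giving the top ranks of the 3 arrays a common level. Quantile normalization, calling on the mean alone and the median of spots moved no count past these limits. Where a value moved and the construction of the alternative does not show why, the cause was not tested. Signal over background was not analysed here, so what brightness limits could only be seen indirectly, from empty values and from ratios of small whole numbers. No paired analysis was possible because each drug has 1 array and no result comes from a test.

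Without centring, 0 genes were enriched under cycloheximide, 1 under rapamycin and 399 depleted under rapamycin. TOR2 then had 9.07 under rapamycin, and GPX2 had 7.46, ALG7 6.32 and GFA1 4.996 under tunicamycin. The folds given for these genes hold relative to the array median only. The stricter threshold left 0 enriched and 37 depleted under cycloheximide and 1 enriched under rapamycin. A 2-fold threshold gave 192, 204 and 185 enriched genes under cycloheximide, rapamycin and tunicamycin, 566 depleted under rapamycin, and 13 enriched in both cycloheximide and rapamycin, 11 in both cycloheximide and tunicamycin and 8 in both rapamycin and tunicamycin. The count that independent lists would share was not computed at this threshold, so these overlaps do not show that the same strains were selected. With the spread of the non-essential list as the unit, 20 were enriched under cycloheximide, 2 under rapamycin (without SHE3) and 15 under tunicamycin. MSS4 and RPT5 were among those under cycloheximide, and TBF1 among those under tunicamycin. Leaving out exact 0 gave 5 enriched under cycloheximide. Keeping the code as a ratio gave 12, 5 and 9 enriched genes, which held 0 of the 2, 3 of the 3 and 5 of the 5 reported. With 1 measured probe sufficing, 5, 9 and 14 were enriched and 599 depleted under rapamycin.

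Turning the sign exchanges the calls by construction, giving 625, 259 and 569 enriched, 2, 3 and 5 depleted, and 177, 512 and 142 enriched in both drugs of the pairs cycloheximide and rapamycin, cycloheximide and tunicamycin, and rapamycin and tunicamycin. The number of the 18 lists with a median under the 1st percentile of random lists, 15, 14 and 15 in the main setting, became 0, 0 and 1. Drawn from the union of the essential lists, it was 0, 0 and 0 of 15. Within those lists the rank correlations were 0.704, 0.595 and 0.713. The sign was not turned for single genes, where it only changes the sign.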

Other observations

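The test of GFA1 partners was chosen after the enriched genes were known, and was split by gene after a first version, a count of 0 enriched among the 3 partners, had been read. The test of the depth of fall was chosen with correlations over all genes known but before its own value was seen. The counts of empty values were chosen after.

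The pathway from fructose 6-phosphate to UDP-GlcNAc, the sugar donor of Alg7, did not move as a unit under tunicamycin. GFA1, its first enzyme, was enriched at 5.87 ± 0.86 (n = 2), while GNA1 was depleted at -4.85 ± 0.53 and PCM1 at -6.47 ± 1.29, and QRI1 had -2.56 ± 4.03 with probes at 0.29 and -5.41. Enrichment of GNA1 and PCM1 together with GFA1 is argued against, since the higher of their values, -4.85, lay below 0 by more than its SD, as did the other. For QRI1, at -2.56, the spread between probes leaves it open.

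Strains of the essential lists differed in how far they fell, with quartiles of -3.94 and -2.003 under cycloheximide, -7.62 and -2.73 under rapamycin and -5.80 and -2.39 under tunicamycin. A property of each strain common to the arrays, such as its abundance in the untreated pool, may set this depth. The lowest of the 3 rank correlations between arrays over these lists was 0.595, above the 0.5 named beforehand. Untreated DNA shared by the arrays would raise it too, and abundance itself was not measured. The correlations cover all members with a value, including those that were not depleted, and were not computed over depleted members alone. They therefore cannot tell a common depth of fall from members that fell or did not fall alike on the arrays.

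On the rapamycin array 0 measured spots had a deposited log2 ratio below -10 and 406 lay between -10 and -9, where the cycloheximide and tunicamycin arrays held 0 and 33. Among rapamycin spots whose partner probe lay at or below -3 units, 387 of 1477 (26.2%) were empty, against 1358 of 13482 (10.1%) where the partner lay within 2 units of the median. On the cycloheximide array these shares were 3.05% and 15.1%, and on the tunicamycin array 5.74% and 13.5%. Probe pairs with 1 probe beyond 2 units above and the other beyond 2 units below numbered 20 of 6487, 35 of 7130 and 39 of 6823 on the cycloheximide, rapamycin and tunicamycin arrays. Unnamed probe pairs gave 36, 21 and 33 depleted pairs of 621.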
